A study of Mus musculus with 9 samples.

How the data were processed

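The series measured polyadenylated RNA of 9 mouse samples in 3 groups of 3. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded mRNA kit. The submitters' processing notes name TopHat, Cufflinks and the mm10 build, with no versions or settings given in the sources used here. The authors deposited FPKM per gene and library (fragments per kilobase scaled to the mapped fragments of a library), with positions and gene names. A second deposited table holds group means and other values, the standard deviations, of the same FPKM, and recomputed values differed from it by at most 1.8e-12 and 7.3e-12. Samples were matched to columns by their labels.

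The table had 48640 rows, of which 26982 were above 0 in some library. Excel-style date names on 27 rows were repaired from gene identifiers, and 49 identifiers stood on several rows. Identifiers matched the GENCODE M21 annotation of the same build in 99.3% of rows. Positions are given as 1-based. Pseudogene rows held 37.54% to 50.83% of FPKM per library, and reads shared with parent genes cannot be told apart in this unit. An exact 0 can be a failed estimate, since 315 rows had a 0 in a library and over 20 FPKM in another. Such genes are reported as listed at 0. Depth was not recoverable from these values, so no counting interval is given.

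Tests were run in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) for the 13808 rows with a mean of at least 1 FPKM over all libraries, in 1 fit of 3 group means with a trended variance prior and no block. A gene was called at a two-sided Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. A gene near 0 in some groups was tested only if others were high enough, which favours calls in that direction among such genes. "Rose" and "fell" mean called. The median standard error was 0.157.

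Before the data were examined, 22 gene lists, the comparisons, the tests and the rule for named genes were fixed. The lists were YAP/TAZ targets, Hippo components, naive and primed pluripotency, fibroblast, epithelial, keratinocyte, trophoblast, extraembryonic endoderm, neural, early mesoderm, leukocyte, endothelial, actin and SRF target, matrix, proliferation, CDK inhibitor and p53 target, germline, imprinted, interferon, two-cell-stage, and glycolysis and hypoxia genes. Lists with at least 5 tested members were tested with limma's camera with a correlation preset at 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other tested genes, and fry tests whether its genes move, on balance, one way. The rule for named genes took 21 fixed genes, the 2 called members with the largest change in each direction of each list (or the member with the smallest p where none was called), and the 6 largest changes each way among genes whose groups did not overlap and whose higher group had a mean of at least 10 FPKM, without gene-model names. Other called members are named where a count was 5 or fewer, and Dab2 and Sparc as well, all chosen after their values were seen. A few named genes are not reported here.

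Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-ratio scaling, quantile normalization, a fit of the compared groups alone, a replicate block, array weights, other variance priors, a test against the fold threshold (treat), and each library left out. Alternatives chosen after seeing the data were rows above 0 in all libraries, no X and Y rows, protein-coding rows rescaled to equal totals, 2 doubted iPSC libraries left out, and a per-library loess correction on the GC content of the longest transcript, known for 99.7% of tested rows.

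The fits were tested on simulated data with 200 changed genes among 13808, made from the mean of each gene over all libraries and its residual spread. For colonies against YAP-culture iPSCs, 32% of changes of 1 on the log2 scale, 92% of 1.5, 84% of 2 and 96% of 3 were recovered, with 3 false calls. For colonies against control iPSCs the shares were 26%, 88%, 80% and 96% with 1 false call, and for the iPSC groups 38%, 76%, 88% and 98% with 2. A list of 20 random genes shifted by 1, among 22 such lists, was called in each comparison, with 1 false list call, in the colonies against control iPSCs. The simulated noise was independent between genes, while the estimated correlation within the real lists reached 0.781 (two-cell-stage genes). The simulation therefore cannot show how often correlated lists are called falsely. Figures were drawn with matplotlib from the same tables.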

Results

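RNA-seq libraries were made from 3 kinds of mouse colonies that came out of reprogramming cultures of embryonic fibroblasts after 75 days. Control induced pluripotent stem cells (iPSCs) came from cultures given an empty vector and carried an active Oct4:GFP reporter. YAP-culture iPSCs came from cultures given a vector for Yes-associated protein (YAP), the transcriptional co-activator of the Hippo pathway. They had lost YAP overexpression per the sample titles. The column headings of the deposited values mark both iPSC groups as Oct4+ and the YAP-culture iPSCs also as YAP+. Which of these describes their YAP status was not settled. YAP colonies were the mCherry-marked, non-pluripotent colonies of the YAP cultures, which were kept on feeder cells with doxycycline. Each group had 3 libraries. The values were FPKM, and they summed to between 509321 and 634471 per library. The read depth is unknown, because FPKM totals are not read counts. The labels did not state that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

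The libraries fell into 2 sets, the YAP colonies and the iPSCs. Across the 13808 tested genes, the median Pearson correlation of log2(FPKM + 1) was 0.970 within the colonies, 0.965 within the control iPSCs and 0.944 within the YAP-culture iPSCs. It was 0.938 between the iPSC groups, 0.746 between the colonies and the YAP-culture iPSCs, and 0.744 between the colonies and the control iPSCs. Genes are not independent replicates, so these values describe the libraries only. YAP-culture iPSC replicate 3 reached 0.969 with control replicate 2, against 0.944 and 0.934 with the other libraries of its own group. Control iPSC replicate 3 stood apart in ribosomal RNA rows, which held 5.46% of its FPKM against at most 0.81% in the other libraries.

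The comparison of YAP colonies with YAP-culture iPSCs asked how colony types from YAP-transduced cultures differed. The labels did not state whether they came from the same cultures or embryos. Xist, the RNA that coats the inactive X chromosome, was 166 ± 32.2 FPKM in the colonies and 1.09 ± 0.493 in these iPSCs. A difference of sex or embryo may therefore add to the changes below. The naive pluripotency genes fell in the colonies, with 24 of 28 tested members lower and none higher. Dppa5a, a marker of naive pluripotent cells (chromosome 9, 78367052 to 78368177, mm10), went from 4660 ± 458 FPKM to 4.11 ± 1.17 (SD, n = 3). Zfp42, also called Rex1 (chromosome 8, 43295063 to 43306980), went from 283 ± 18.7 to 0.355 ± 0.179 FPKM. Tdgf1, a Nodal co-receptor, Dnmt3l, a cofactor of de novo DNA methylation, and Esrrb, a nuclear receptor of the naive network, fell by 8.12, 7.31 and 6.30 on the log2 scale. The core factors, which the list also holds, changed less. Values of Pou5f1, Sox2, Klf4 and Myc, here and in the other comparisons, can hold transcripts of doxycycline-driven reprogramming factors besides those of the native genes. Nanog was lower at 132 ± 22.6 FPKM in the colonies and 308 ± 17.4 in the iPSCs, and Sox2 fell by 2.13 on the log2 scale. Pou5f1, which encodes Oct4, was 281 ± 13.9 against 156 ± 50.6 FPKM and was not called, with a log2 fold change of 0.89. Klf4 was 89.6 ± 20.5 against 73.8 ± 12.5 FPKM, also not called. Myc, the growth-promoting transcription factor, rose from 20.6 ± 6.30 to 401 ± 60.1 FPKM.

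**Figure D1:**
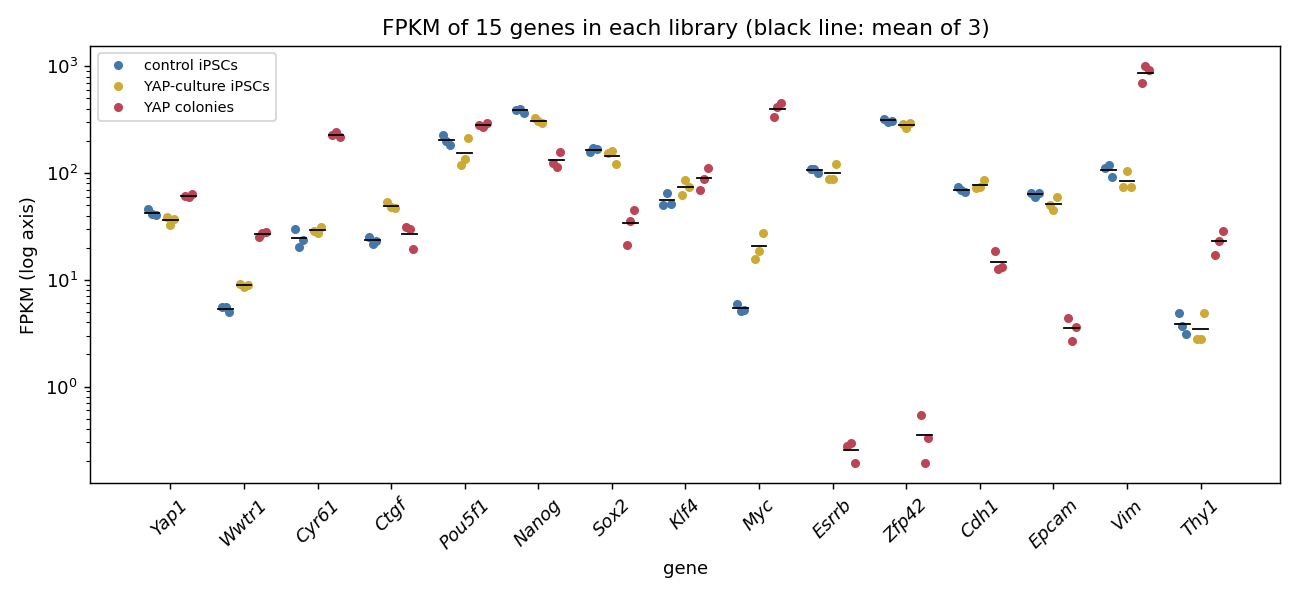
FPKM (log axis) of 15 genes in each of the 9 libraries, coloured by group, with a black line at the mean of 3 libraries. Zfp42 and Esrrb lie below 1 FPKM in all 3 colony libraries, while Pou5f1 lies at 267 FPKM or more there.

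Genes of the Hippo pathway and its output rose in part. Yap1 itself (chromosome 9, 7931999 to 8004596) was 61.0 ± 1.97 FPKM in the colonies and 36.1 ± 3.36 in the YAP-culture iPSCs. Its log2 fold change of 0.74 had an adjusted p of 2.11e-04 in limma and stayed below the fold threshold. How much of the vector's YAP transcript the Yap1 row holds is unknown. Yap1 values here and in the other comparisons therefore do not measure YAP overexpression. Wwtr1, which encodes the YAP paralog TAZ, rose from 8.93 ± 0.276 to 26.9 ± 1.48 FPKM. Of 16 tested YAP/TAZ target genes 10 were higher, among them Cyr61 at 229 ± 12.6 against 29.1 ± 1.78 FPKM, the receptor kinase gene Axl at 29.4 ± 5.49 against 1.30 ± 0.186, and Tgfb2. Gadd45a, a stress-response gene, was the 1 member that fell. Ctgf, another common YAP target, was 26.8 ± 6.31 FPKM in the colonies and 49.4 ± 3.23 in the iPSCs. Its log2 fold change of -0.885 had an adjusted p of 1.71e-03 in limma, and it was not called because of the fold threshold. Of 21 Hippo components 7 rose, among them Vgll4 and Ptpn14, and none fell. Ankrd1 was below the expression filter.

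Most tested mesenchymal and contractile genes rose while most tested epithelial genes fell. Of 15 fibroblast and mesenchymal genes 13 were higher, including the intermediate filament gene Vim at 872 ± 164 against 84.1 ± 16.7 FPKM, Col5a2 at 30.8 ± 9.66 against 0.178 ± 0.00658, and Thy1 at 22.9 ± 5.82 against 3.49 ± 1.19. The metalloproteinase gene Mmp2 fell. The list holds 25 genes. Below the filter were Col1a2, Pdgfra, Pdgfrb, Postn, Lum, Twist1, Twist2, Prrx1, Snai2 and Fap, with means of 0.03 to 0.95 FPKM over all libraries. Col1a1 rose but was only 2.60 ± 0.704 FPKM in the colonies. Of 16 actin and SRF target genes 12 rose, among them the smooth muscle actin gene Acta2 at 78.3 ± 14.1 against 0.517 ± 0.286 FPKM, and 1, Tpm2, fell. Tagln, another smooth muscle gene of the list, was listed at 0 in all 6 iPSC libraries and at 58.6, 57.6 and 49.7 FPKM in the colonies. Without YAP-culture iPSC replicate 3 the log2 fold change of Tpm2 was -0.85 and it was not called. Of 21 epithelial genes 15 fell, with Cdh1 (E-cadherin) at 14.8 ± 3.46 against 77.3 ± 7.44 FPKM and Epcam at 3.57 ± 0.848 against 51.4 ± 7.69, and 1, the desmosome gene Dsp, rose. In the matrix list of 17 genes 10 rose and 2 fell, with Serpine2 and Fbln2 higher and Spp1 (osteopontin) and Fn1 (fibronectin) lower. All 7 tested members of the extraembryonic endoderm list rose, but these were Dab2, Sparc and basement membrane genes such as Col4a1 and Col4a2, and the transcription factor gene Gata6 was below the filter. Without the filter the median log2 fold change of this list was 0 (adjusted p = 0.293).

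Cell-cycle inhibitors, imprinted genes and germline genes separated the groups as well. Of 15 CDK inhibitor and p53 target genes 9 rose and none fell, with a log2 fold change of 3.63 for the CDK inhibitor gene Cdkn1a and with Cdkn2a at 44.1 ± 9.87 against 1.06 ± 0.526. Of 20 proliferation genes 3 fell, namely Bub1, Birc5 and Ccnb2, and none rose. Without colony replicate 1 the log2 fold change of Ccnb2 was -0.98 and it was not called. Of 18 imprinted genes 11 rose, led by Dlk1 at 110 ± 26.5 against 0.614 ± 0.210 FPKM and the noncoding RNA Rian, and 2, Phlda2 and Snrpn, fell. Phlda2 was listed at 0 in all 3 colony libraries. All 13 tested germline genes were lower, such as Tex19.1, and all 16 two-cell-stage genes were lower, such as Zscan4f. Sycp3 was listed at 0 in all 3 colony libraries. Of 18 glycolysis and hypoxia genes 8 fell, including the growth factor gene Vegfa, and 1, the oxygen sensor gene Egln3, rose. The glycolytic gene Pfkp was listed at 0 in all 3 colony libraries, which can be a failed estimate.

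Among markers of other lineages, most tested neural genes rose, while the other lists were mixed or had few tested members. Of 8 neural genes 7 rose, among them Map2, and 1, Olig2, fell. In the trophoblast list of 10 genes Tfap2a rose and Krt7, Tfap2c, Plet1 and Eomes fell. In the endothelial list of 5 genes Tek and Ecscr rose and Vwf, Eng and Egfl7 fell, with Eng listed at 0 in all 3 colony libraries. In the primed pluripotency list of 9 genes Lef1, Sall2 and Zic2 rose and Dnmt3b fell. In the interferon list of 6 genes Bst2 rose and Stat2 and Oas1a fell. Lists with fewer than 5 tested members got no list test. Among 4 keratinocyte genes Perp rose and Krt17 and Sfn fell, among 3 leukocyte genes Laptm5 rose and Cd68 and Lyz2 fell, and Hand1, the tested early mesoderm gene, was not called. Without YAP-culture iPSC replicate 3 or colony replicate 2, Lyz2 had log2 fold changes of -0.95 and -0.96 and was not called. The largest changes outside the lists included higher Gpm6b, Ccnd2, Aldh1a1 and Cd109 and lower Fabp3-ps1 and Tdgf1-ps1. The last 2 are pseudogenes that can share reads with their parent genes.

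Among 13808 genes, 4184 passed the threshold in limma, 2185 higher and 1999 lower in the colonies. Adjusted over the list alone, the counts were the same except that 12 imprinted genes were higher. In the list test with a preset correlation, naive pluripotency (median log2 fold change -4.10, adjusted p = 5.15e-14), germline (-2.83, 1.06e-07) and fibroblast genes (2.24, 5.70e-06) were called. These 3 held, at adjusted p = 0.0441, 0.0441 and 0.0498 with an estimated correlation. The other called lists did not hold with an estimated correlation. Fry called each of them in the same direction, with adjusted p of at most 0.0106 (proliferation genes). YAP/TAZ targets had a median of 1.57 (adjusted p = 4.12e-04) and adjusted p = 0.208 with an estimated correlation, and Hippo components 0.83 (2.81e-05) and adjusted p = 0.199 with an estimated correlation. Actin genes had 1.49 (4.49e-05) and adjusted p = 0.212 with an estimated correlation, and epithelial genes -2.07 (2.98e-05) and adjusted p = 0.287 with an estimated correlation. Two-cell-stage genes had -3.06 (7.16e-08) and adjusted p = 0.229 with an estimated correlation, extraembryonic endoderm genes 1.59 (3.16e-04) and adjusted p = 0.208 with an estimated correlation, and imprinted genes 1.86 (2.16e-03) and adjusted p = 0.208 with an estimated correlation. CDK inhibitor genes had 1.13 (7.63e-04) and neural genes 1.99 (4.28e-03), each with adjusted p = 0.122 with an estimated correlation. Matrix genes had 1.32 (9.61e-03) and adjusted p = 0.286 with an estimated correlation, proliferation genes -0.51 (8.17e-03) and adjusted p = 0.551 with an estimated correlation, and glycolysis genes -0.83 (4.70e-03) and adjusted p = 0.441 with an estimated correlation. Trophoblast (adjusted p = 0.450), primed (0.615), endothelial (0.862) and interferon genes (0.997) were not called by camera, and the interferon median of 0.15 and mean of -0.21 differed in sign. The trophoblast and endothelial medians and means were below 0, where fry gave a higher direction. Fry called endothelial (adjusted p = 1.23e-03) and primed genes (4.35e-04) higher and interferon genes lower (0.0363), and not trophoblast genes (0.522). Also with the preset correlation, the matrix call was lost with a minimum of 5 FPKM (adjusted p = 0.0755) and the imprinted call on rescaled protein-coding genes (0.0522). The count was 2108 with a pseudocount of 5, and lower genes outnumbered higher ones under median-ratio scaling (2086 against 2078) and without YAP-culture iPSC replicate 2 (2063 against 2017).

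**Figure D2:**
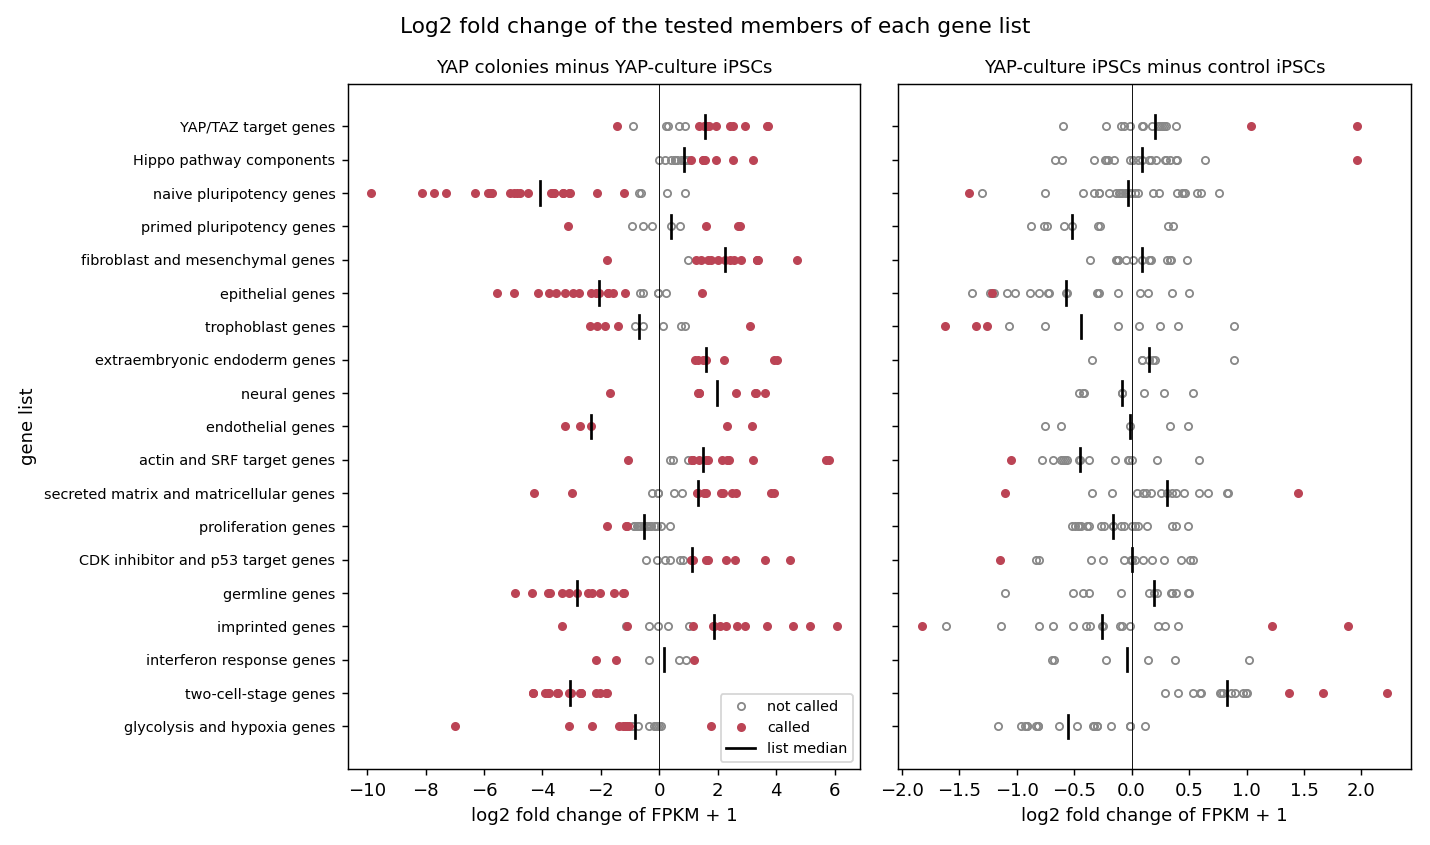
Log2 fold change of FPKM + 1 for each tested member of the gene lists with at least 5 tested members, with called members filled, others open, and a black line at the list median. Naive pluripotency genes lie at a median of -4.10 between YAP colonies and YAP-culture iPSCs and at -0.03 between the iPSC groups.

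The comparison of YAP colonies with control iPSCs asked the same of iPSCs from empty-vector cultures. Naive pluripotency genes were again lower in 24 of 28 cases, with Zfp42 at 0.355 ± 0.179 against 311 ± 10.8 FPKM and Nanog at 132 ± 22.6 against 386 ± 17.5. Pou5f1 was 281 ± 13.9 against 203 ± 21.4 FPKM and was not called. Myc rose from 5.46 ± 0.444 to 401 ± 60.1 FPKM. Yap1 was 61.0 ± 1.97 against 42.5 ± 2.86 FPKM, with a log2 fold change of 0.51 that was not called. Of the YAP/TAZ targets 11 rose, with Cyr61 at 229 ± 12.6 against 24.6 ± 4.93 FPKM and Amotl2 at 36.7 ± 4.81 against 14.8 ± 1.87, and Gadd45a fell. Of the Hippo components 8 rose. Lats2, a Hippo kinase gene, was listed at 0 in all 3 control libraries and at 12.3, 16.8 and 13.5 FPKM in the colonies.

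Of 15 tested fibroblast genes 14 rose and Mmp2 fell, of 21 epithelial genes 17 fell and Dsp rose, and of 16 actin genes 8 rose and Tpm2 fell. In the matrix list 12 rose, and Spp1 and Fn1 were among those that fell. Of 15 CDK inhibitor genes 8 rose, and of 20 proliferation genes 6 fell. All 13 germline genes and 13 of 16 two-cell-stage genes fell. Of 18 imprinted genes 10 rose, with Grb10, a growth-factor adapter gene, at 176 ± 21.0 against 5.27 ± 1.24 FPKM, and Igf2, Phlda2 and Snrpn fell. Glycolysis genes fell in 10 of 18 cases. All 7 extraembryonic endoderm list members rose, while without the filter the list median was -0.05 (adjusted p = 0.279). Among 8 neural genes Map2, Pax6, Ncam1 and Sox11 were among those that rose, and Olig2 fell. Tfap2a rose and Krt7, Tfap2c, Plet1, Eomes and Hand1 fell in the trophoblast list, and Hand1 was also the tested early mesoderm gene. Tek and Ecscr rose and Vwf, Eng and Egfl7 fell in the endothelial list. Lef1 and Sall2 rose and Otx2, Dnmt3b and Cldn9 fell in the primed list. Stat2 and Oas1a fell in the interferon list. Perp rose and Krt17 and Sfn fell among keratinocyte genes, and Laptm5 rose and Cd68 fell among leukocyte genes. Rhox5, an X-linked homeobox gene, was 2.13 ± 0.812 against 896 ± 94.8 FPKM, and Emp1, a membrane protein gene, was 465 ± 81.7 against 1.05 ± 0.501.

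In limma 4396 genes passed the threshold, 2051 higher and 2345 lower, and the list counts were the same when adjusted over the list alone. Naive pluripotency (median -4.59, adjusted p = 1.13e-12), germline (-2.64, 8.25e-07) and fibroblast genes (2.28, 2.57e-06) were called, and each held at adjusted p = 0.0410 with an estimated correlation. YAP/TAZ targets had a median of 1.61 (adjusted p = 2.99e-05) and Hippo components 0.94 (8.63e-06), each with adjusted p = 0.144 with an estimated correlation. Epithelial genes had -2.63 (2.57e-06) and adjusted p = 0.262 with an estimated correlation, actin genes 1.18 (6.15e-04) and adjusted p = 0.274 with an estimated correlation, and two-cell-stage genes -2.18 (1.08e-05) and adjusted p = 0.287 with an estimated correlation. Extraembryonic endoderm genes had 2.12 (1.35e-04) and adjusted p = 0.202 with an estimated correlation. Matrix genes had 1.47 (1.68e-03) and imprinted genes 1.44 (4.52e-03), each with adjusted p = 0.222 with an estimated correlation. CDK inhibitor genes had 1.25 (5.82e-04) and neural genes 2.18 (4.26e-03), each with adjusted p = 0.113 with an estimated correlation. Proliferation genes had -0.65 (4.18e-03) and adjusted p = 0.473 with an estimated correlation, and glycolysis genes -1.12 (1.35e-04) and adjusted p = 0.286 with an estimated correlation. Fry called all the lists that camera called, in the same direction, with adjusted p of at most 5.67e-03 (proliferation genes). Trophoblast (adjusted p = 0.115), primed, endothelial and interferon genes (each 0.876) were not called by camera. The primed median of 0.05 and mean of -0.01, and the interferon median of 0.59 and mean of -0.22, differed in sign. Fry called endothelial genes higher (adjusted p = 6.99e-04), though their median and mean were below 0. It called trophoblast (0.0313) and interferon genes (8.20e-03) lower, and not primed genes (0.548). Also with the preset correlation, the imprinted call was lost on rescaled protein-coding genes (adjusted p = 0.0786), and trophoblast genes were called without the filter (6.63e-03). The count was 2259 with a pseudocount of 5. The majority of called genes turned from lower to higher with quantile normalization (2186 against 2054), on rescaled protein-coding genes (2137 against 1728) and on genes above 0 in all libraries (1857 against 1673).

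The changes of the colonies against the iPSC groups resembled each other. Across genes, the log2 fold changes correlated at Pearson 0.928 and Spearman 0.894, where unchanged groups that share the 3 colony libraries gave 0.5 in simulation. The covariance was 1.71 against 0.0407 simulated, a difference of 1.67. Both comparisons called 1772 genes higher and 1751 lower, where independent lists would share 325 and 339, and 0 genes were called in opposite directions. Both comparisons use the same 3 colony libraries, which are too few to divide between them.

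The comparison of YAP-culture iPSCs with control iPSCs asked whether iPSCs from YAP cultures differed from those of empty-vector cultures. Cth, which encodes a cysteine-synthesis enzyme, was 74.7 ± 11.6 FPKM in YAP-culture iPSCs and 14.7 ± 2.68 in controls. The imprinted gene Grb10 was 21.9 ± 2.20 against 5.27 ± 1.24 FPKM, the channel gene Trpm1 16.6 ± 3.89 against 2.08 ± 0.764, and Myc 20.6 ± 6.30 against 5.46 ± 0.444, all higher. Rhox9, an X-linked homeobox gene, was lower at 3.93 ± 1.33 against 28.0 ± 6.37 FPKM. Yap1 was 36.1 ± 3.36 against 42.5 ± 2.86 FPKM and was not called (log2 fold change -0.23, adjusted p = 0.159 in limma). Pou5f1, Nanog, Sox2, Esrrb and Zfp42 were not called. Jmjd6 was listed at 52.6, 45.8 and 46.6 FPKM and Ears2 at 12.9, 11.6 and 11.3 in the controls, and both were listed at 0 in all YAP-culture iPSC and colony libraries. Itfg2 was listed at 0 in the 3 YAP-culture iPSC libraries and had a mean of 10.7 ± 0.493 FPKM in controls, and Lats2 was listed at 0 in all 3 controls and at 3.24, 3.18 and 2.30 FPKM in YAP-culture iPSCs.

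Few members of the gene lists were called. The YAP/TAZ targets Ctgf and Lats2 were higher, with Ctgf at 49.4 ± 3.23 against 23.5 ± 1.77 FPKM, and Lats2 was also the 1 Hippo component called. Plagl1 and Grb10 were higher and Igf2 lower among imprinted genes. Zfp352, Tcstv1 and Tcstv3 were higher among two-cell-stage genes, and 4 were when adjusted over the list alone. Bgn was higher in the matrix list, Lyz2 higher among leukocyte genes, Dppa3 lower among naive genes (2 adjusted over the list alone), Cdkn2a lower among CDK inhibitor genes, and Tpm2 lower among actin genes. Krt18 was lower among epithelial genes, with 5 lower when adjusted over the list alone. Tfap2c, Hand1 and Esx1 were lower among trophoblast genes, with 4 when adjusted over the list alone, and Hand1 was also the tested mesoderm gene. Adjusted over the list alone, 3 imprinted genes were lower, as was 1 each of the keratinocyte, germline and glycolysis genes. The primed, fibroblast, extraembryonic endoderm, neural, endothelial, proliferation and interferon lists had 0 called members.

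In limma 192 genes passed the threshold, 70 higher and 122 lower, against 4202 at an unadjusted p below 0.05. Log2 fold changes correlated with the GC content of transcripts across genes (Spearman -0.603), and called-lower genes had a median GC of 54.6% against 49.4% of those tested. Two-cell-stage genes (median 0.83, adjusted p = 2.33e-08), glycolysis genes (-0.55, 6.45e-05), matrix genes (0.31, 0.0174) and primed genes (-0.52, 0.0412) were called, each with adjusted p = 0.725 with an estimated correlation. Epithelial genes (-0.57, 8.66e-03) and actin genes (-0.45, 0.0423) each had adjusted p = 0.796 with an estimated correlation, and YAP/TAZ targets (0.20, 0.0412) adjusted p = 0.743 with an estimated correlation. Of these lists fry called two-cell-stage and glycolysis genes (each adjusted p = 0.0433) and primed genes (0.0105), in the same directions. It did not call the others (0.0567 to 0.161). Fry also called trophoblast genes lower (0.0433). After a GC correction chosen after seeing the data, the epithelial (adjusted p = 0.0511, range over the other settings with a preset correlation 1.29e-03 to 0.0886), primed (0.199, range 0.0124 to 0.302) and actin calls (0.300, range 0.0124 to 0.128) were lost. Fibroblast (0.0456, range 0.0524 to 0.790) and extraembryonic endoderm genes (2.19e-03, range 0.134 to 0.910) were then called higher. The actin call was also lost without control replicate 1 or 3 or YAP-culture iPSC replicate 1 or 2 (up to 0.102), and the primed call without control replicate 3 or YAP-culture iPSC replicate 3 (up to 0.302). The YAP/TAZ call was lost without control replicate 2 or YAP-culture iPSC replicate 3 (up to 0.210), and the matrix call without YAP-culture iPSC replicate 3 (0.115). These 4 calls were also lost without X and Y genes, and those of YAP/TAZ, primed and matrix genes with array weights (each 0.152). Without the filter trophoblast genes were called (7.47e-03). Trophoblast (adjusted p = 0.195), Hippo (0.206), extraembryonic endoderm (0.442), fibroblast (0.498), germline (0.575), proliferation (0.669), interferon (0.702), naive (0.764) and neural genes (0.903) were not called by camera as deposited, nor were CDK inhibitor, endothelial and imprinted genes (each 0.679). The list test gave a higher direction for naive, neural and endothelial genes, whose medians (-0.03, -0.08 and -0.02) and means were below 0. CDK inhibitor genes had a median of 0.003 and a mean of -0.09, and fry gave a higher direction for imprinted genes, whose median was -0.25.

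The count of 192 rested on single libraries. It was 52 without control replicate 1, 52 without control replicate 3, 95 and 104 without YAP-culture iPSC replicates 1 and 2, and 1048 without YAP-culture iPSC replicate 3. It was 106 without colony replicate 2 and 106 without colony replicate 3, which enter through the shared spread. It was 44 without control replicate 3 and YAP-culture iPSC replicate 2 together, which stood apart in ribosomal RNA and in the share of their 10 highest rows, and 36 in a fit of the 6 iPSC libraries alone. Of 27 named and called genes, 13 kept their call with any 1 library left out, including Cth, Grb10, Trpm1, Myc, Rhox9, Plagl1, Bgn and Tcstv3. Jmjd6, Ears2, Itfg2 and Lats2 were also among the 13, but each was listed at 0 in all libraries of a group. Leaving out 1 library cannot show whether such a 0 is a failed estimate. The other 14 of the 27 genes lost their call in some fits, among them the following. Cdkn2a and Tpm2 lost it without any 1 of the controls, YAP-culture iPSC replicates 1 and 2 and colony replicates 2 and 3 (highest adjusted p 0.133 and 0.112), as did Igf2 (0.157). Khdc3 lost it without any control, YAP-culture iPSC replicate 2 or any colony replicate (0.148). Krt18 lost it without control replicate 1 or 3, YAP-culture iPSC replicate 1 or 2 or any colony replicate (0.145). Hand1 lost it without control replicate 1 or 3, YAP-culture iPSC replicate 1 or 2 or colony replicate 2 or 3 (0.108), and Rhox6 without the same libraries other than YAP-culture iPSC replicate 2 (0.117). Ctgf (0.0937) and Zfp352 (0.104) lost it without any control or YAP-culture iPSC replicate 1 or 2. Tfap2c (0.0828) lost it without control replicate 1 or 3 or YAP-culture iPSC replicate 1 or 2. Lyz2 lost it without control replicate 2 or 3 or YAP-culture iPSC replicate 1 (0.0901), and Dppa3 (0.0626) and Sfrp1 (0.0626) without control replicate 1 or 3. The log2 fold changes stayed near those with all libraries where these calls were lost, from -2.93 to -3.53 for Khdc3 (-3.46 with all), 0.99 to 1.10 for Ctgf (1.04) and -0.95 to -1.24 for Krt18 (-1.21), and were unchanged without a colony library. In the fit of the 6 iPSC libraries alone, Myc (adjusted p = 0.0554) and Tcstv3 (0.0591) of those 13 genes lost their call.

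**Figure D3:**
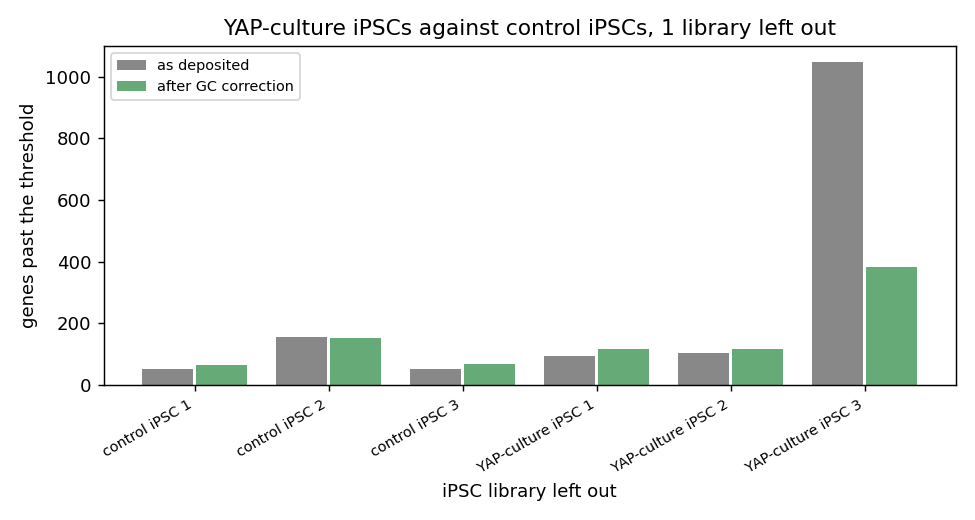
Number of genes past the threshold between YAP-culture and control iPSCs (bars from 0) when the iPSC library on the horizontal axis was left out, as deposited and after a GC correction. The count without YAP-culture iPSC replicate 3 is 1048 as deposited and 382 after the correction.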

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

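The GC correction, the rescaled protein-coding rows, the rows above 0, the fit without X and Y rows and the fit without 2 doubted iPSC libraries were chosen after seeing the data. With a pseudocount of 5, a minimum of 5 FPKM and treat, the colonies differed from YAP-culture iPSCs in 2108, 2421 and 2369 genes (4184 as reported) and from control iPSCs in 2259, 2599 and 2496 (4396). Fewer genes were tested under the higher minimum, treat tests a stricter hypothesis by construction, and a larger pseudocount shrinks low genes. All other settings kept these counts within 1.5 times, with leave-one-out ranges of 4072 to 4421 and 4225 to 4421. The iPSC groups differed in 192 genes as reported, in 57, 114 and 12 under those 3 settings, 36 in the fit of the compared groups alone, 922 with array weights, 44 without 2 doubted libraries, and 52 to 1048 with 1 library left out. For array weights the cause was not tested. Of called genes between the iPSC groups, 36.5% were higher as reported, 51.6% with quantile normalization, 51.9% without control replicate 1, 53.7% without YAP-culture iPSC replicate 1 and 13.3% without YAP-culture iPSC replicate 3. For colonies against control iPSCs the share rose from 46.7% to 51.6% with quantile normalization, 55.3% on rescaled protein-coding genes and 52.6% on genes above 0, so the majority direction depends on scaling and filter. Protein-coding rescaling shifted the fold changes of protein-coding genes by a median of 0.122 for colonies against control iPSCs. The replicate numbers gave no sign of pairing. Deviations of same-numbered libraries correlated between -0.141 and 0.188, and those of differently numbered libraries between -0.182 and 0.212. Such values cannot exclude a pairing, since each deviation is taken from a mean of only 3 libraries. A replicate block gave 4184, 4398 and 160 genes. Without a filter, the median of extraembryonic endoderm genes was 0 against YAP-culture iPSCs (adjusted p = 0.293) and -0.052 against control iPSCs (0.279), where more members near 0 FPKM were tested. Between the iPSC groups, genes not called changed sign for Zfp42 (0.011, quantile), Col1a1 (-0.013, array weights), Thy1 (0.007 without control replicate 1, down to -0.345 without YAP-culture iPSC replicate 3, 0.148 with the GC correction) and Esrrb (0.129, GC correction), and the cause was not tested. The correlation of the colony changes was 0.935 with a pseudocount of 0.1 (0.928), and the median correlation of colony and iPSC libraries was 0.729 by Spearman (0.746), and the cause was not tested. Over the settings chosen before, named genes kept their direction and side of the threshold in 1760 cases, lost a call in 25 and gained one in 7 for colonies against YAP-culture iPSCs. The numbers were 1754, 16 and 0 against control iPSCs, and 964, 130 and 6 between the iPSC groups. Unknown read depth limits what can be said of low genes.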

Other observations

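The gene families, the Y-linked genes and the tests on Y loss, carried-over iPSCs, reprogramming factors, GC content with and without replicate 3, the wrong label on GC-corrected values and a mixture were chosen only after the results were seen, so counts and no p-values are given for families. Among those tested, Hox genes, which encode positional identity along the body axis, were higher in the YAP colonies. All 21 tested members were called higher against YAP-culture iPSCs and 20 against control iPSCs, with 0 called lower and 0 called by limma between the iPSC groups. The filter largely fixed these counts for genes near 0 FPKM in the iPSCs, which were tested only if high in the colonies. Hox genes below the filter were not counted. Hoxa9 was 21.2 ± 5.33 FPKM in the colonies and 0.0544 ± 0.0393 in YAP-culture iPSCs, and Hoxc6 16.8 ± 2.36 against 0.0550 ± 0.0952 (SD, n = 3). Hoxa10 was listed at 0 in the YAP-culture iPSCs.

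Zinc finger genes on chromosome 4 were lower in the colonies, with 18 of 27 called lower against YAP-culture iPSCs and 17 against control iPSCs, and 2 called higher in each. Zfp979 was 0.203 ± 0.0698 against 94.7 ± 25.6 FPKM in YAP-culture iPSCs. Reads shared between similar zinc finger genes were not examined. Of 313 zinc finger genes on other chromosomes, 55 were called higher and 32 lower against YAP-culture iPSCs, and 53 higher and 28 lower against control iPSCs. Annexin genes were higher in 6 of 9 cases and lower in 1 against YAP-culture iPSCs, and higher in 5 and lower in 2 against control iPSCs. H2 genes, of the major histocompatibility complex, were lower in 6 of 14 cases and higher in 1 in each colony comparison, but lower in 4 of 14 after quantile normalization and 4 of 12 on rescaled protein-coding genes in both. All 3 tested Rhox genes were lower against YAP-culture and control iPSCs, and 2 of 3 were lower in YAP-culture than in control iPSCs. In the 2 colony comparisons, the Hox counts and those of chromosome 4 were the same under median-ratio scaling, quantile normalization, rescaled protein-coding genes and the GC correction. These settings all kept the same expression filter.

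Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460375 to 103483217), was 166 ± 32.2 FPKM in the colonies against 1.09 ± 0.493 in YAP-culture and 0.502 ± 0.0638 in control iPSCs, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty reached at most 0.373 FPKM in a colony library. Loss of the Y chromosome from male cells predicts low Xist, but the lowest colony library had 88.4 times the Xist of the highest iPSC library. A female origin of the colonies and a male origin of the iPSCs predicts 1 active X on each side, and the median of X genes lay 0.097 above that of autosomal genes at its farthest, against control iPSCs. Colonies and iPSCs may therefore come from embryos of different sex, a hypothesis under which sex or embryo adds to every colony comparison. Without X and Y genes, 13229 of 13808 genes were left, and 3984 and 4178 were called against YAP-culture and control iPSCs. Few tested genes lie on X and Y, so these counts cannot decide the hypothesis, which also concerns autosomal genes.

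Pou5f1, Nanog and Sox2 stayed at 157%, 38.2% and 21.7% of the mean iPSC level in the colonies. Carried-over iPSCs would bring their abundant transcripts, but Dppa5a, Zfp42, Esrrb and Tdgf1 reached at most 0.249% (Esrrb). Transcripts of doxycycline-driven reprogramming factors could add to Pou5f1, Sox2, Klf4 (138%) and Myc (3077%), and cannot be told apart from those of the native genes, since a gene's value holds both. Factors made in equal number would keep Sox2 at or above the iPSC level too, which its 21.7% was not, but equal number is not known. A native program of the colonies stays open and untested.

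The calls between the iPSC groups depended on single libraries, and 3 technical explanations were weighed. The test fixed before its result was met in its first part, a correlation of fold changes with GC (-0.603), and not in its second, a count falling by over 1.5 times after a GC correction (151 against 192), but neither part measures the dependence on single libraries. Without YAP-culture iPSC replicate 3, the 1048 calls fell to 382 after the correction, so GC may account for much of that rise, but 382 was still 2.53 times the 151 with all libraries and counts without 1 other iPSC library ran from 65 to 152, which argues against GC as the whole cause. For a wrong label on that library, the test fixed before was undecided. The library lay on the YAP-culture side in 20.8% of genes called without it. Held-out controls did so in at most 14.8%, and the other YAP-culture libraries in at least 87.5%. On GC-corrected values it lay there in 43.2% (15.1% and 88.0%). Most genes fixed before lay outside the controls in this library. Among them were Ctgf (47.0 FPKM, controls 21.8 to 25.4), Myc (27.7, controls 5.14 to 5.96), Wwtr1 (8.97, controls 4.97 to 5.60) and Nanog (292, controls 366 to 400). Some did so narrowly, such as Zfp42 (297, controls 303 to 323). Pou5f1 (213, controls 184 to 226), Krt8 (2.69, controls 2.17 to 4.12) and Thy1 lay among the controls, as did Gata6 and Cdx2 below 1 FPKM. Together these values argue against a library like these controls. A mixture with control RNA would give 1 position between the groups for all genes, and cannot be told apart from a library with a wider spread of its own, since the interquartile range of positions was 1.46 times the largest of another library on GC-corrected values and 1.06 times as deposited, and another origin stays open, as untested.

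For each comparison the 6 libraries allow 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many calls, with 4113 genes for colonies against YAP-culture iPSCs (highest other split 2), 4391 against control iPSCs (4) and 36 between the iPSC groups (9), in fits of 6 libraries.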
